A study of Homo sapiens with 8 samples.

How the data were processed

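RNA of HEL cells, a human erythroleukaemia line with a mutated JAK2, was profiled after 24 hours with the vehicle DMSO, with ruxolitinib (0.5 µM), with pevonedistat (1 µM) or with both drugs at those doses. There were 8 libraries in 4 groups of 2. Total RNA was taken with a column kit and DNase treatment and sequenced on a NovaSeq instrument, per the labels' protocols. The labels state neither how ribosomal RNA was avoided nor whether the library kit marks strand, so genes that overlap or lie antisense to each other are uncertain. They say that treatments were done in duplicate and do not say whether the duplicates were separate cultures, so every p-value here measures only the spread between these samples.

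Reads were aligned with STAR 2.5.1a to GRCh38 and edgeR was among the tools used, per the submitters' processing notes; neither the counting program nor the annotation is stated. The deposited counts are whole numbers, 1 column per library, for 55209 table entries named by Ensembl gene. Of these, 116 entries repeating a gene ID were dropped, which left 55093 genes. A second deposited table holds log2 values for 14956 genes. Each of its columns differed from the log2 CPM of the matching library, computed with 0.5 added to each count, by a constant offset. It also holds log2 fold changes and adjusted p-values for the group comparisons, per the file headers; the authors' test and the filter that chose those genes are not stated. All values in the text come from the count table unless the deposited table is named.

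Gene symbols came from the deposited tables. Positions are those of GENCODE release 29 on GRCh38, which may not be the annotation the authors counted with. Of the gene IDs, 55086 had a position there and 7 had none. Library totals ran from 42599051 to 90504602 counts, and the tested genes held at least 99.949% of each. Shares of counts carry Wilson 95% binomial confidence intervals, which cover counting error only.

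Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling, filterByExpr by group and a single model of all 8 libraries with 4 group means and no covariate. This left 21776 genes. Adjusted p-values are Benjamini-Hochberg values over those genes within a comparison, and "rose", "fell" and "changed" mean an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Such an SE can be too small where a large change starts from few counts. Levels are in CPM on TMM-scaled library sizes, given as mean ± SD of 2 libraries. Comparisons were each drug and the combination against DMSO, the combination against each drug, and the interaction, which is the change with pevonedistat in the presence of ruxolitinib minus that change in its absence, on the log2 scale. Pearson correlations and regression slopes of log2 fold changes across genes are descriptions without a p-value, since genes are not independent replicates. Those between the effects of a drug with and without the other were taken between comparisons that share no library.

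The comparisons, the test, the alternatives, 20 gene lists (574 genes, 14 of them on more than 1 list) and the rule for named genes were fixed before the data were examined. The lists cover JAK-STAT5 output, NF-kB targets, NRF2 targets, p53 targets, DNA replication, mitosis, erythroid, megakaryocyte, granulocyte and monocyte genes, lymphocyte and stromal markers, interferon-stimulated genes, cholesterol synthesis, amino-acid response (ATF4 targets), the unfolded-protein response, hypoxia-inducible genes, ribosome biogenesis, neddylation, the BCL2 family, MAPK output and mitochondrially encoded mRNAs. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 20 lists within a comparison, and again with a correlation estimated from the data; fry was run as a further value. Members were also counted by direction, over all genes and adjusted over the list alone.

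In each pairwise comparison the genes named were the 10 with the largest rise and the 10 with the largest fall among protein-coding genes that changed, had a mean of at least 5 CPM and did not overlap between groups; in each list, the 4 members with the largest changes at a mean of at least 1 CPM; and a fixed set of key genes of both drug targets and of the pathways above. For the interaction they were the 5 largest in each direction. Some lower-ranked ones are left out for length, and some that met the rule are not reported here. Genes of the Y chromosome and XIST were not considered. Genes named outside this rule, including those of 9 gene families, were chosen after their values were seen.

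Alternatives were RLE size factors, total-count scaling, no filter on low counts (39693 genes), a mean of at least 5 CPM (10811 genes), DESeq2 1.42.0, limma-voom, the authors' deposited log2 values with limma-trend, only the groups compared, the replicate number as a block, and each library left out in turn. Leaving mitochondrial genes out was added after their shares were seen. With 2 libraries per group, no group was large enough for tests of other splits of the samples or of single deviating libraries.

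The edgeR step was tested on simulated data of 20792 genes, with 200 changed for each of ruxolitinib, pevonedistat and the interaction. Over all levels it recovered 63%, 57% and 55% of 2-fold changes for ruxolitinib against DMSO, pevonedistat against DMSO and the interaction, and 55%, 48% and 40% of 1.5-fold changes. At 5 CPM or more it recovered 100% of 2-fold changes in each of these 3, and 98.1%, 91.8% and 81.6% of 1.5-fold changes. False calls were 2.5%, 0.9% and 7.8% of calls. Far fewer genes changed in the simulation than in the data, where 12621 of 21776 did with pevonedistat, so these rates may not carry over. In the simulated test of 20 lists, camera called 1 of the 1 list that was changed and 0 others. Simulated genes were drawn independently of each other, so this does not show how camera behaves with correlated genes. In the data 3 of 76 list calls held with an estimated correlation. Tables and figures were made with Python 3.11.15.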

Results

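HEL cells depend on signalling from a mutated JAK2. Ruxolitinib blocks the kinases JAK1 and JAK2. Pevonedistat blocks the NEDD8-activating enzyme, and with it the cullin-RING ubiquitin ligases that mark many short-lived proteins for degradation. The series asks how each drug and their combination change gene expression in these cells after 24 hours, and its title links pevonedistat to the NF-kB pathway. Total counts were 55077527 and 60771686 in the DMSO libraries, 66914872 and 82847285 with ruxolitinib, 90504602 and 60891592 with pevonedistat, and 77450799 and 42599051 with both drugs (n = 2 per group throughout).

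Libraries separated by pevonedistat first: the first principal component held 88.7% of the variance and the second 5.9%. Mitochondrially encoded RNA took 3.61% ± 0.042 (SD) of counts with DMSO, 4.10% ± 0.064 with ruxolitinib, 7.42% ± 0.035 with pevonedistat and 14.2% ± 4.14 with both drugs. Combination replicate 2 had 17.1% (95% Wilson interval 17.11 to 17.13) and replicate 1 had 11.3%. Replicate 2 was also the library with the fewest counts, and the replicates of this group differed most: the SD of their log2 difference over genes of at least 5 CPM was 0.172, against 0.101 to 0.126 in the other groups. The model shares its estimate of spread over all groups. Its p-values may thus be too small for contrasts with the combination and too large for others. With only the groups compared, 4273 genes instead of 2890 changed for ruxolitinib against DMSO. For the combination against pevonedistat 4777 instead of 5465 did. Numbers of changed genes are therefore also given without combination replicate 2, as are median changes of mitochondrially encoded mRNAs.

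**Figure D1:**
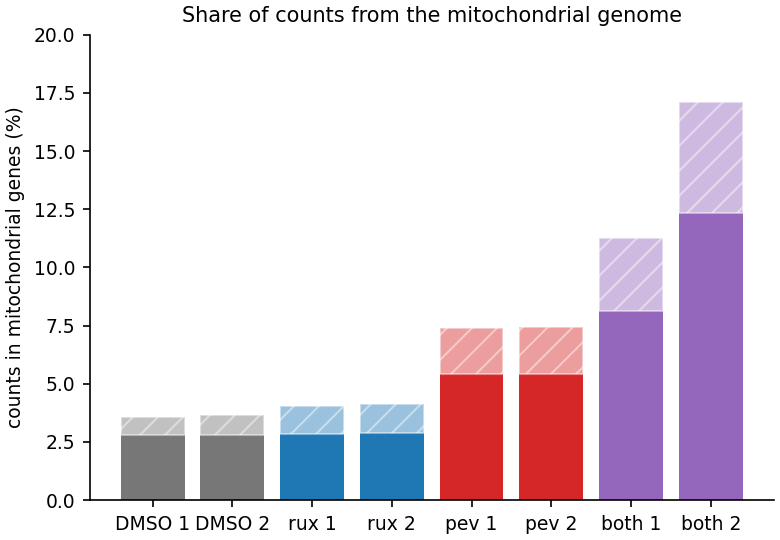
Share of each library's counts in mitochondrially encoded genes (%), for the 8 libraries, with mRNAs as the solid part of the bar and other genes, mainly ribosomal RNAs, as the hatched part. The share was 3.58 and 3.64% with DMSO and 11.27 and 17.12% with both drugs.

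Ruxolitinib against DMSO shows the change with the JAK inhibitor alone. JAK activity itself was not measured. Among the 10 largest falls were genes that report MAPK signalling: the ETS transcription factors ETV4 (log2 fold change -3.71 ± 0.11 SE, from 42.3 ± 5.48 to 3.26 ± 0.48 CPM) and ETV5 (-3.56 ± 0.11), the immediate-early factor EGR1 (-2.56 ± 0.14) and DUSP6, a phosphatase that switches off ERK (-2.49 ± 0.11). Feedback inhibitors and kinases induced by STAT factors fell with them, led by SOCS3 (-2.00 ± 0.11), SOCS1 (-1.53 ± 0.20) and the survival kinase PIM1 (-1.02 ± 0.07, from 594 ± 44.5 to 294 ± 12.4 CPM). Red-cell genes rose, among them the embryonic globin HBZ (1.51 ± 0.15), the adult globin HBA2 (1.33 ± 0.09, from 180 ± 3.36 to 452 ± 31.0 CPM) and the transferrin receptor TFRC (1.11 ± 0.07). HBA1 and HBA2, and likewise HBG1 and HBG2, are near-identical, so counts may be divided between them in either way.

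Of 24 MAPK output genes, 14 fell, 0 rose and 10 did not pass the test, with 14 down and 1 up adjusted over the list alone. CCND1, the cyclin D1 gene, fell most (-4.05 ± 0.27). Camera called the list lower (adjusted p = 3.93e-51), and the call held with an estimated correlation (adjusted p = 0.0148). The erythroid list had 33 of 43 members up and 1 down (36 and 1 adjusted over the list alone), with adjusted p = 6.06e-53 and 0.0213 with an estimated correlation. JAK-STAT5 output had 15 of 21 members down and 0 up (15 and 2 adjusted over the list alone), with adjusted p = 2.49e-28 and 0.0483 with an estimated correlation. PIM2 (-0.69 ± 0.07), the anti-apoptotic BCL2L1 (-0.59 ± 0.06), SOCS2 (-0.37 ± 0.08, a call lost without ruxolitinib replicate 1, at -0.32) and CISH (-0.34 ± 0.07) fell modestly, and JAK2 itself rose (0.56 ± 0.07). MYC was at 0.15 ± 0.06, adjusted p = 0.0999. It passed with limma-voom, with DESeq2, with only the groups compared, and without combination replicate 1 (0.14) or 2 (0.16).

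Amino-acid response genes, which ATF4 drives, fell in 19 of 31 cases and rose in 0 (20 and 0 adjusted over the list alone), including DDIT4 (-2.16 ± 0.15), ATF3 (-1.83 ± 0.20) and the glutathione-degrading CHAC1 (-1.70 ± 0.18). The camera call (adjusted p = 4.44e-16) was lost with an estimated correlation (adjusted p = 0.133). Hypoxia-inducible genes fell in 15 of 30 cases and rose in 0 (18 down and 2 up adjusted over the list alone), with BHLHE40 (-2.12 ± 0.08), the glucose transporter SLC2A3 (-1.29 ± 0.07) and the angiogenic factor VEGFA (-1.19 ± 0.08), adjusted p = 1.42e-17 and adjusted p = 0.111 with an estimated correlation. Cholesterol genes had 11 of 29 down and 3 up (14 and 3 adjusted over the list alone; MSMO1 -0.76 ± 0.08), adjusted p = 0.00207 and adjusted p = 0.542 with an estimated correlation. NF-kB targets had 11 of 39 down and 2 up (13 and 4 adjusted over the list alone), adjusted p = 0.00207 and adjusted p = 0.41 with an estimated correlation. Mitosis genes had 7 of 40 down and 0 up (10 and 0 adjusted over the list alone), adjusted p = 0.0054 and adjusted p = 0.689 with an estimated correlation. The call ended without DMSO replicate 1 (adjusted p = 0.151) or ruxolitinib replicate 1 (adjusted p = 0.0565). Granulocyte and monocyte genes had 4 of 15 down and 0 up (5 and 0 adjusted over the list alone; CD33 -0.64 ± 0.06), adjusted p = 0.0064 and adjusted p = 0.148 with an estimated correlation.

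Among megakaryocyte genes 9 of 30 fell and 7 rose (9 and 8 adjusted over the list alone): the collagen receptor GP6 (-2.06 ± 0.09) and MMRN1 (-1.24 ± 0.07) fell while TUBB1 (0.97 ± 0.08) and GP5 (0.95 ± 0.09) rose, adjusted p = 0.0176 and adjusted p = 0.427 with an estimated correlation. That call ended without ruxolitinib replicate 1 (adjusted p = 0.0712). Lymphocyte and stromal markers, listed as a check for other cell types, had 5 of 16 down and 2 up (6 and 2 adjusted over the list alone), adjusted p = 0.0249 and adjusted p = 0.175 with an estimated correlation. Their call ended without ruxolitinib replicate 2 (adjusted p = 0.063) and at 5 CPM or more (adjusted p = 0.334). Interferon-stimulated genes moved both ways, 6 of 38 up and 9 down (6 and 9 adjusted over the list alone), with the antigen-processing genes PSMB9 (0.76 ± 0.07) and TAP1 (0.66 ± 0.06) up, and the list was not called (adjusted p = 0.54). Other large rises were in the metalloprotease PAPPA (1.63 ± 0.10), the lectins ITLN2 (1.59 ± 0.12) and ITLN1 (1.39 ± 0.08), the red-cell pyruvate kinase PKLR (1.42 ± 0.10) and the water channel AQP1 (1.42 ± 0.13). Large falls outside the lists were in the surface protein CD24 (-3.60 ± 0.13), the phosphate transporter SLC34A1 (-3.13 ± 0.15) and WNT11 (-2.98 ± 0.12).

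In edgeR's test 2890 of 21776 genes changed with ruxolitinib, 1574 up and 1316 down, with 150 up and 225 down by 2-fold or more. The up share was 54.5%, and 42.9% with total-count scaling. The count was 1573 without DMSO replicate 1, 1763 without ruxolitinib replicate 1 and 1590 without ruxolitinib replicate 2.

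**Figure D2:**
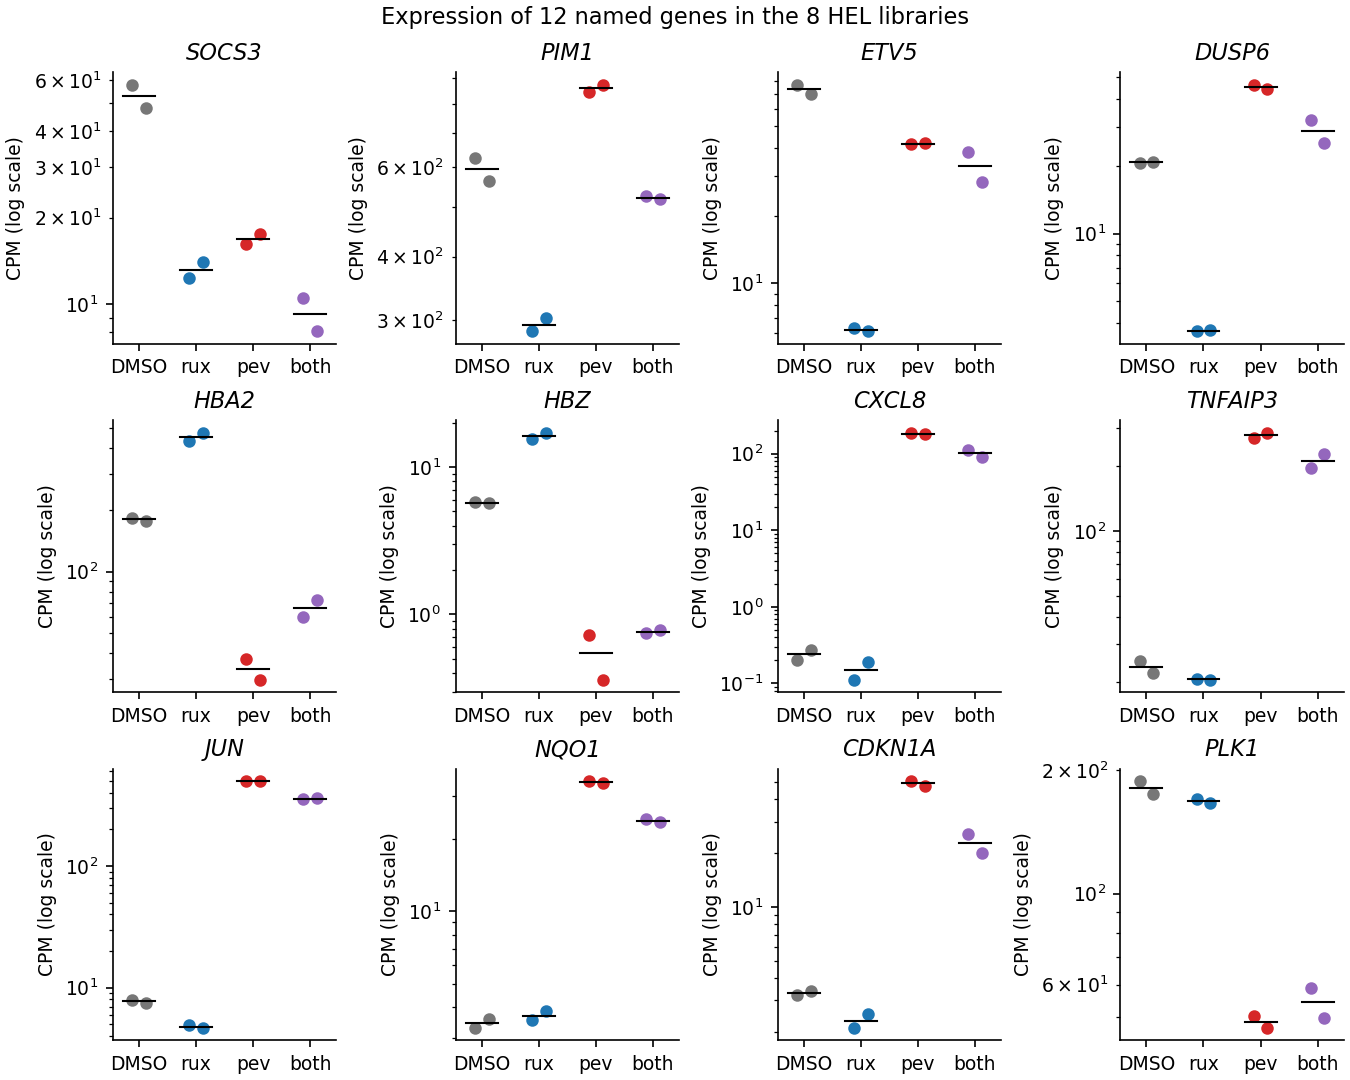
Scaled counts (CPM) on a log axis for 12 named genes in each of the 8 libraries, with points for libraries and a line at the group mean (rux, ruxolitinib; pev, pevonedistat; both, combination). SOCS3, PIM1 and ETV5 are lower with ruxolitinib than with DMSO, and CXCL8, JUN and CDKN1A are higher in the 4 libraries with pevonedistat than in the 4 without.

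Pevonedistat against DMSO shows the change with the neddylation inhibitor alone. Neddylation itself was not measured. The stress-kinase phosphatase DUSP8 had 2 and 4 counts in the DMSO libraries and 8541 and 5350 with pevonedistat (log2 fold change 10.90 ± 0.19 SE). The neutrophil chemokine CXCL8 went from 0.239 ± 0.048 to 183 ± 6.12 CPM (9.56 ± 0.15), and the AP-1 subunit JUN from 7.70 ± 0.25 to 498 ± 2.44 CPM (6.01 ± 0.08). CXCL8 had 12 and 18 counts in the DMSO libraries, so the SEs of DUSP8 and CXCL8 are likely too small. ATF3 (6.24 ± 0.11), the TGF-beta inhibitor SMAD7 (5.46 ± 0.19), DHRS2 (5.16 ± 0.20), PHLDA1 (4.93 ± 0.09), the EGF-receptor ligand AREG (4.63 ± 0.17) and the chemokine CXCL3 (4.31 ± 0.10) also rose. The largest falls were in PKLR (-3.78 ± 0.13), SHISA7 (-3.68 ± 0.12), the receptor kinase FGFR3 (-3.65 ± 0.09), the glycolytic regulator PFKFB4 (-3.51 ± 0.10) and IGFBP5, an abundant binding protein of insulin-like growth factors (-3.43 ± 0.08, from 1313 ± 19.8 to 122 ± 4.58 CPM).

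Of 39 NF-kB target genes, 27 rose, 6 fell and 6 did not pass the test (28 up and 6 down adjusted over the list alone), with a median log2 fold change of 1.36. Besides CXCL8 and CXCL3, the prostaglandin synthase PTGS2 (4.11 ± 0.09), IER3 (3.85 ± 0.16), the feedback inhibitor TNFAIP3 (3.56 ± 0.08, from 23.5 ± 2.17 to 277 ± 11.3 CPM) and the apoptosis inhibitor BIRC3 (3.26 ± 0.19) rose. NFKBIA, which encodes the inhibitor that holds NF-kB in the cytoplasm, fell (-0.45 ± 0.09), and the subunit genes NFKB1 (0.63 ± 0.06) and RELA (0.61 ± 0.06) rose. The camera call (adjusted p = 2.01e-12) was lost with an estimated correlation (adjusted p = 0.242). With total-count scaling the median of all genes lay at -0.24, and the list's median at 1.18.

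Lists of targets of other stress regulators were called higher at the preset correlation. MAPK output genes had 19 of 24 up and 3 down (19 and 3 adjusted over the list alone), with FOS at 3.67 ± 0.34, adjusted p = 8.4e-11 and adjusted p = 0.242 with an estimated correlation. Amino-acid response genes had 23 of 31 up and 3 down (25 and 3 adjusted over the list alone), with CHAC1 (3.36 ± 0.14), DDIT3, which encodes the stress factor CHOP (3.29 ± 0.11), and the cystine transporter SLC7A11 (3.23 ± 0.09), adjusted p = 3.6e-15 and adjusted p = 0.242 with an estimated correlation. NRF2 targets had 16 of 30 up and 5 down (16 and 7 adjusted over the list alone), with the quinone reductase NQO1 (3.32 ± 0.10), TXNRD1 (1.15 ± 0.08) and the haem oxygenase HMOX1 (1.10 ± 0.12), adjusted p = 0.000105 and adjusted p = 0.332 with an estimated correlation. The p53 target list had 16 of 25 up and 5 down (16 and 5 adjusted over the list alone), adjusted p = 8.17e-07 and adjusted p = 0.242 with an estimated correlation. Its members include the growth factor GDF15 (4.30 ± 0.20), the cyclin-dependent kinase inhibitor CDKN1A (3.89 ± 0.12, from 3.30 ± 0.14 to 49.2 ± 2.11 CPM) and the death receptor TNFRSF10B (2.90 ± 0.21). BCL2-family genes had 7 of 15 up and 4 down (7 and 4 adjusted over the list alone), and those that rose most encode pro-apoptotic proteins: BMF (3.01 ± 0.11), BBC3 (2.59 ± 0.10), BAK1 (2.24 ± 0.09) and PMAIP1 (1.38 ± 0.08). That list had adjusted p = 0.0183, adjusted p = 0.332 with an estimated correlation and adjusted p = 0.147 at 5 CPM or more.

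Several lists of cell-division, lineage and lipid genes were called lower. Mitosis genes had 34 of 40 down and 2 up (34 and 4 adjusted over the list alone), with KIF20A (-2.43 ± 0.09), the kinase PLK1 (-1.89 ± 0.07), BUB1 (-1.80 ± 0.08) and the cyclin CCNB1 (-1.65 ± 0.07), adjusted p = 3.26e-14 and adjusted p = 0.332 with an estimated correlation. DNA replication genes moved both ways, 20 of 48 up and 18 down (20 and 19 adjusted over the list alone), with E2F1 (1.89 ± 0.06) and the licensing factor CDC6 (1.16 ± 0.06) up, and the list was not called (adjusted p = 0.724). Erythroid genes had 26 of 43 down and 11 up (27 and 11 adjusted over the list alone), among them HBZ (-3.32 ± 0.20, and -3.98 without pevonedistat replicate 1), HBA2 (-2.41 ± 0.09), the glycophorin GYPB (-1.93 ± 0.08) and the fetal globin HBG1 (-1.36 ± 0.08), adjusted p = 5.93e-08 and adjusted p = 0.242 with an estimated correlation. Megakaryocyte genes had 16 of 30 down and 6 up (16 and 6 adjusted over the list alone), adjusted p = 0.00182 and adjusted p = 0.332 with an estimated correlation. TUBB1 (-2.65 ± 0.09) and the integrins ITGB3 (-2.28 ± 0.07) and ITGA2B (-1.03 ± 0.06) were down, and THBS1 (2.97 ± 0.08) was up. Cholesterol and fatty-acid genes had 24 of 29 down and 2 up (24 and 2 adjusted over the list alone), with LSS (-2.13 ± 0.07), FADS2 (-1.95 ± 0.07) and FASN (-1.54 ± 0.07), adjusted p = 5.08e-09 and adjusted p = 0.332 with an estimated correlation. Hypoxia-inducible genes had 15 of 30 down and 12 up (15 and 12 adjusted over the list alone), with PFKFB4, ALDOC (-2.82 ± 0.08) and BNIP3 (-2.68 ± 0.09) down, adjusted p = 0.0153 and adjusted p = 0.529 with an estimated correlation.

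JAK-STAT5 output genes moved both ways with pevonedistat, 10 of 21 up and 9 down (10 and 9 adjusted over the list alone; list adjusted p = 0.738). PIM2 (-1.67 ± 0.07) and SOCS3 (-1.65 ± 0.10) fell, while SOCS2 (0.64 ± 0.08), PIM1 (0.53 ± 0.07) and CISH (0.48 ± 0.07) rose. JAK2 (-0.62 ± 0.07) and MYC (-1.11 ± 0.06) fell. Of 42 genes of neddylation and cullin ligases, 25 rose and 10 fell (25 and 11 adjusted over the list alone; list adjusted p = 0.22). The NEDD8-conjugating enzyme UBE2M (1.33 ± 0.06) and DCUN1D3 (1.61 ± 0.12) rose, and both subunits of the drug's target enzyme, NAE1 (-0.68 ± 0.07) and UBA3 (-0.47 ± 0.07), fell. NEDD8 was at 0.36 ± 0.10 (adjusted p = 0.0023), a call lost with total-count scaling (0.19), without DMSO replicate 2 (0.28) or without pevonedistat replicate 1 (0.23). CDT1, whose protein cullin ligases degrade, rose at the mRNA level (0.50 ± 0.06). Unfolded-protein-response genes had 10 of 22 up and 12 down (10 and 12 adjusted over the list alone), with XBP1 (1.45 ± 0.08) up and PDIA6 (-1.38 ± 0.07) down, and ribosome biogenesis genes had 15 of 37 up and 19 down (15 and 19 adjusted over the list alone). Neither list was called (adjusted p = 0.969 and 0.738). Interferon-stimulated genes, granulocyte and monocyte genes, and lymphocyte and stromal markers were not called either (adjusted p = 0.82, 0.969 and 0.373).

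The share of mitochondrial RNA was higher with pevonedistat, beside the rises and falls of the lists above: mitochondrially encoded mRNAs had 12 of 13 up and 0 down (12 and 0 adjusted over the list alone), with MT-CYB at 1.55 ± 0.13 and a median of 1.10, adjusted p = 0.000318, adjusted p = 0.528 with an estimated correlation and adjusted p = 0.061 when tested among genes of at least 5 CPM. MT-ND6, encoded on the other strand of the mitochondrial genome, was at 0.08 ± 0.09 (adjusted p = 0.472). In edgeR's test 12621 genes changed with pevonedistat, 6270 up and 6351 down, with 2362 up and 2965 down by 2-fold or more. The up share was 49.7%, and 39.1% with total-count scaling, which moved the median of all genes from -0.065 to -0.237.

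**Figure D3:**
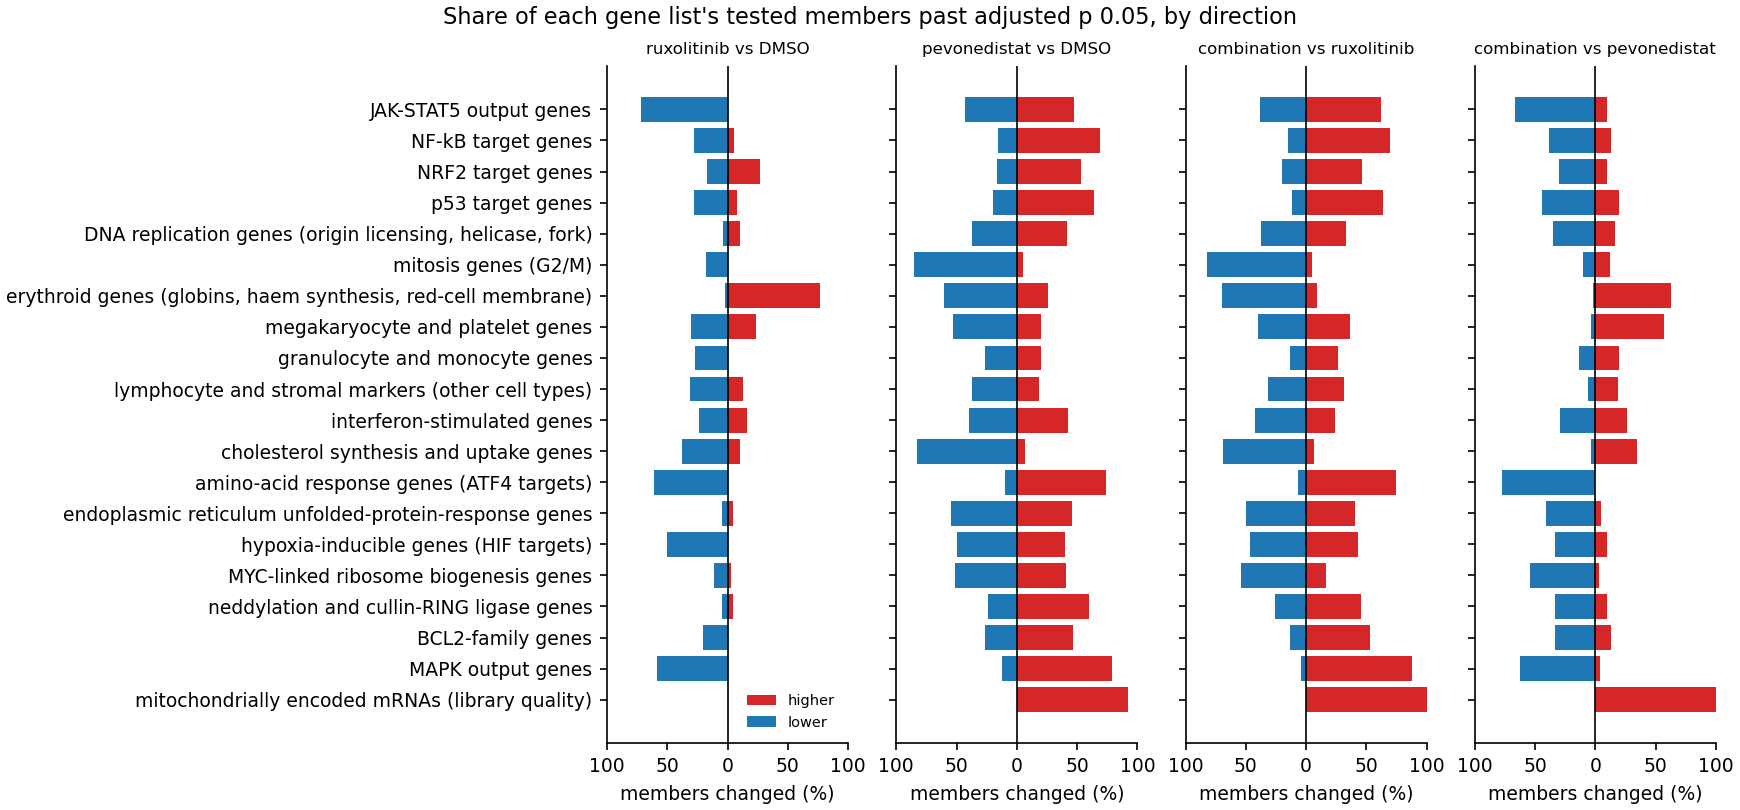
Share of each list's tested members (%) that were higher (red, to the right) or lower (blue, to the left) at adjusted p under 0.05, for 20 gene lists in 4 comparisons. Erythroid genes go up with ruxolitinib (33 of 43) and mostly down with pevonedistat (26 of 43), and MAPK output genes go down with ruxolitinib (14 of 24) and up with pevonedistat (19 of 24).

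The combination against DMSO gives the net change with both drugs. CXCL8 (8.72 ± 0.15), JUN (5.54 ± 0.08), ATF3 (5.25 ± 0.11), the T-cell costimulator TNFRSF9 (4.31 ± 0.20), CXCL3 (3.95 ± 0.10) and BIRC3 (3.69 ± 0.19) rose, as did DUSP8, to 61.3 ± 9.47 CPM. PFKFB4 (-3.02 ± 0.09), HBZ (-2.91 ± 0.20), ALDOC (-2.82 ± 0.09), the cytoskeletal ADD2 (-2.53 ± 0.10) and the biotin enzyme gene PC (-2.46 ± 0.09) fell. SOCS3 fell to its lowest group mean, 9.29 ± 1.75 CPM (-2.49 ± 0.11). PIM2 (-1.83 ± 0.07), MYC (-0.92 ± 0.06) and BCL2L1 (-0.43 ± 0.06) fell, and PIM1 was slightly lower (-0.19 ± 0.07, adjusted p = 0.0201), a call lost without DMSO replicate 1 (-0.11) or combination replicate 2 (-0.15). JAK2 was at -0.12 ± 0.07 (adjusted p = 0.177). It passed with total-count scaling (-0.33), at 5 CPM or more (-0.20) and with the deposited log2 values (-0.16).

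NF-kB targets had 27 of 39 up and 7 down with both drugs (27 and 7 adjusted over the list alone), adjusted p = 3.57e-15 and adjusted p = 0.233 with an estimated correlation. Mitosis genes had 36 of 40 down and 3 up (36 and 3 adjusted over the list alone), with KIF20A at -1.94 ± 0.09, adjusted p = 6.46e-22 and adjusted p = 0.233 with an estimated correlation. Cholesterol genes had 27 of 29 down and 2 up (27 and 2 adjusted over the list alone), with LSS at -1.58 ± 0.06, adjusted p = 1.42e-10 and adjusted p = 0.233 with an estimated correlation. Amino-acid response genes had 18 of 31 up and 5 down (19 and 7 adjusted over the list alone), adjusted p = 1.4e-09 and adjusted p = 0.233 with an estimated correlation. The p53 targets had 15 of 25 up and 3 down (15 and 3 adjusted over the list alone), with CDKN1A at 2.80 ± 0.12 and BTG2 at 2.57 ± 0.07, adjusted p = 5.09e-06 and adjusted p = 0.233 with an estimated correlation. Erythroid genes had 22 of 43 down and 14 up (22 and 14 adjusted over the list alone), with HBA2 at -1.45 ± 0.09, adjusted p = 0.000473 and adjusted p = 0.295 with an estimated correlation. Ribosome biogenesis genes had 22 of 37 down and 7 up (22 and 7 adjusted over the list alone), with the nucleolar NCL at -1.06 ± 0.07, adjusted p = 0.000256 and adjusted p = 0.369 with an estimated correlation. Mitochondrially encoded mRNAs had 13 of 13 up (13 adjusted over the list alone), with MT-CYB at 2.60 ± 0.13 and a median of 2.08 (1.71 without combination replicate 2), adjusted p = 5.02e-18 and adjusted p = 0.233 with an estimated correlation.

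In edgeR's test 10942 genes changed with both drugs against DMSO, 5859 up and 5083 down, with 1702 up and 1590 down by 2-fold or more, and 10106 genes changed without combination replicate 2. The up share was 53.5%, and 35.6% with total-count scaling, which moved the median of all genes from -0.004 to -0.213.

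The combination against ruxolitinib shows what pevonedistat adds in the presence of ruxolitinib. Some genes that ruxolitinib alone had lowered were higher with the combination than with ruxolitinib, such as EGR1 (3.17 ± 0.14), DUSP6 (2.97 ± 0.11), ETV4 (2.80 ± 0.11), DDIT4 (3.79 ± 0.14) and GP6 (2.41 ± 0.09). PIM2 (-1.14 ± 0.07) and SOCS3 (-0.48 ± 0.11) were lower still. Of 24 MAPK output genes, 21 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 2.77, adjusted p = 1.19e-27 and adjusted p = 0.0683 with an estimated correlation. CXCL8 (9.37 ± 0.16), ATF3 (7.08 ± 0.13), JUN (6.22 ± 0.08), SMAD7 (5.42 ± 0.21, and 6.08 without ruxolitinib replicate 2), TNFRSF9 (5.02 ± 0.21, and 5.79 without ruxolitinib replicate 1), PHLDA1 (4.88 ± 0.10) and CHAC1 (4.40 ± 0.16) rose. HBZ (-4.43 ± 0.19), PKLR (-3.84 ± 0.12), ADD2 (-3.58 ± 0.10), FGFR3 (-3.23 ± 0.09), HBA2 (-2.78 ± 0.09) and the steroidogenic STAR (-2.70 ± 0.07) fell.

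Erythroid genes had 30 of 43 down and 4 up (30 and 4 adjusted over the list alone), adjusted p = 8.45e-20 and adjusted p = 0.103 with an estimated correlation. NF-kB targets had 27 of 39 up and 6 down (28 and 6 adjusted over the list alone), with TNFAIP3 at 3.36 ± 0.08 and CXCL2 at 3.86 ± 0.16, adjusted p = 7.65e-19 and adjusted p = 0.0683 with an estimated correlation. Amino-acid response genes had 23 of 31 up and 2 down (23 and 2 adjusted over the list alone), adjusted p = 7.65e-19 and adjusted p = 0.126 with an estimated correlation. The p53 targets had 16 of 25 up and 3 down (16 and 4 adjusted over the list alone), with GDF15 at 4.80 ± 0.28, adjusted p = 9.66e-08 and adjusted p = 0.171 with an estimated correlation. BCL2-family genes had 8 of 15 up and 2 down (8 and 2 adjusted over the list alone), with BBC3 at 2.51 ± 0.10, adjusted p = 0.0015 and adjusted p = 0.26 with an estimated correlation. Mitosis genes had 33 of 40 down and 2 up (34 and 2 adjusted over the list alone), with PLK1 at -1.63 ± 0.07, adjusted p = 3.12e-16 and adjusted p = 0.3 with an estimated correlation. Cholesterol genes had 20 of 29 down and 2 up (22 and 2 adjusted over the list alone), adjusted p = 1.14e-06 and adjusted p = 0.358 with an estimated correlation. Mitochondrially encoded mRNAs rose here too, 13 of 13 (13 adjusted over the list alone), with a median of 2.14 (1.72 without combination replicate 2), adjusted p = 1.33e-16 and adjusted p = 0.217 with an estimated correlation. BCL2L1 was at 0.16 ± 0.06 (adjusted p = 0.0322), a direction that turned with total-count scaling. The call was lost without DMSO replicate 1 or 2 (0.16 in both), ruxolitinib replicate 1 (0.12) or combination replicate 1 (0.12). It was also lost with RLE size factors (0.14), no filter on low counts (0.15), at 5 CPM or more (0.09) and with only the groups compared (0.16).

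In edgeR's test 10913 genes changed between the combination and ruxolitinib, 5812 up and 5101 down, with 1841 up and 1609 down by 2-fold or more, and 10021 genes changed without combination replicate 2. The up share was 53.3%, and 38.6% with total-count scaling, which moved the median of all genes from -0.002 to -0.176.

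The combination against pevonedistat shows what ruxolitinib adds in the presence of pevonedistat. Genes that were lower with both drugs than with pevonedistat alone included the hypoxia factor EPAS1 (-2.04 ± 0.12, from 31.2 ± 0.35 to 7.50 ± 0.72 CPM), GDF15 (-2.19 ± 0.17), PHLDA1 (-1.60 ± 0.07), ETV4 (-1.21 ± 0.09), IER3 (-1.18 ± 0.13), CDKN1A (-1.10 ± 0.10) and CXCL8 (-0.84 ± 0.08). Some platelet and red-cell genes were higher, among them the platelet tubulin TUBB1 (1.76 ± 0.09), the blood-group gene SMIM1 (1.61 ± 0.10), GP5 (1.41 ± 0.09), GYPB (1.01 ± 0.08), HBA2 (0.96 ± 0.09) and ITGB3 (0.82 ± 0.07). The largest rises were in EXOC3L4 (2.38 ± 0.24, and 3.02 without pevonedistat replicate 2), SHISA7 (1.96 ± 0.13) and PAPPA (1.88 ± 0.11). MTRNR2L10 (1.72 ± 0.29, and 0.67 without combination replicate 2) is uncertain, since it resembles mitochondrial ribosomal RNA and its level in the combination was 14.5 ± 10.8 CPM.

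Amino-acid response genes had 24 of 31 down and 0 up (25 and 0 adjusted over the list alone), adjusted p = 3.38e-21 and adjusted p = 0.11 with an estimated correlation. JAK-STAT5 output genes had 14 of 21 down and 2 up (15 and 2 adjusted over the list alone), with SOCS3 (-0.84 ± 0.11), SOCS2 (-0.72 ± 0.08), PIM1 (-0.71 ± 0.07) and CISH (-0.62 ± 0.07), adjusted p = 3.74e-10 and adjusted p = 0.153 with an estimated correlation. MAPK output genes had 15 of 24 down and 1 up (16 and 1 adjusted over the list alone), with CCND1 at -1.58 ± 0.29, adjusted p = 1.3e-12 and adjusted p = 0.11 with an estimated correlation. Megakaryocyte genes had 17 of 30 up and 1 down (19 and 3 adjusted over the list alone), adjusted p = 8.27e-14 and adjusted p = 0.11 with an estimated correlation. Erythroid genes had 27 of 43 up and 1 down (27 and 2 adjusted over the list alone), adjusted p = 1.36e-13 and adjusted p = 0.11 with an estimated correlation. Ribosome biogenesis genes had 20 of 37 down and 1 up (26 and 1 adjusted over the list alone), with RRP12 at -0.89 ± 0.07, adjusted p = 3.9e-11 and adjusted p = 0.205 with an estimated correlation. NF-kB targets had 15 of 39 down and 5 up (17 and 5 adjusted over the list alone), with PTGS2 at -0.86 ± 0.08, adjusted p = 0.00329 and adjusted p = 0.436 with an estimated correlation. Among them TNFAIP3 (-0.39 ± 0.07) fell while IL1B (1.29 ± 0.09) rose. BIRC3 was at 0.42 ± 0.15 (adjusted p = 0.0378), a call lost without pevonedistat replicate 1 (0.43) or 2 (0.42) or combination replicate 2 (0.17). It was also lost with RLE size factors (0.38), total-count scaling (0.38), DESeq2 (0.39) or the deposited log2 values (0.40). Mitochondrially encoded mRNAs had 13 of 13 up (13 adjusted over the list alone), with MT-CYB at 1.05 ± 0.13 and a median of 0.99 (0.58 without combination replicate 2), adjusted p = 1.59e-20 and adjusted p = 0.153 with an estimated correlation.

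In edgeR's test 5465 genes changed between the combination and pevonedistat, 2588 up and 2877 down, with 356 up and 123 down by 2-fold or more, and 4932 genes changed without combination replicate 2. The up share was 47.4%, and 36.6% with DESeq2; it was 32.9% without combination replicate 1 and 51.0% without replicate 2.

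The interaction asks, gene by gene, whether the change with pevonedistat differed in the presence of ruxolitinib. It passed for 3135 genes in edgeR's test, 1507 higher and 1628 lower, with 323 higher and 64 lower by 2-fold or more. The largest positive values were in ETV5 (3.24 ± 0.14), SLC34A1 (2.88 ± 0.21), CD24 (2.61 ± 0.17), GP6 (2.51 ± 0.12) and ETV4 (2.49 ± 0.14). Among the largest negative ones were RAB5IF (-1.26 ± 0.21), the prion protein gene PRNP (-1.18 ± 0.19), UBXN10 (-1.17 ± 0.13) and ADD2 (-1.16 ± 0.14). Of 39 NF-kB targets 4 were higher and 4 lower (6 and 6 adjusted over the list alone), and camera did not call the list (adjusted p = 0.374). Camera looks for a shared direction, so this does not show that the members' response was unaltered. For CXCL8 (-0.19 ± 0.47, adjusted p = 0.855), TNFAIP3 (-0.20 ± 0.11, adjusted p = 0.251) and BIRC3 (0.28 ± 0.26, adjusted p = 0.558) the interaction did not pass. The count was 2080 without DMSO replicate 1, 1889 without ruxolitinib replicate 2 and 3508 without combination replicate 2. Positive values were 48.1% of those that passed, 36.4% with RLE size factors, 33.6% with DESeq2 and 55.4% at 5 CPM or more. Which direction was the more frequent thus depended on the processing.

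Across the 21776 genes, log2 fold changes of pevonedistat with ruxolitinib (combination against ruxolitinib) correlated with those without it (pevonedistat against DMSO), with Pearson's r = 0.762, a slope of 0.688 and the same sign in 82.5% of genes. At 5 CPM or more r was 0.925 and the slope 0.78. For ruxolitinib with and without pevonedistat r was 0.128 and the slope 0.142, and at 5 CPM or more r was 0.353 and the slope 0.391. Over all genes that slope was 0.084 without DMSO replicate 2 and 0.092 without ruxolitinib replicate 1. These comparisons share no library, and genes are not independent replicates.

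**Figure D4:**
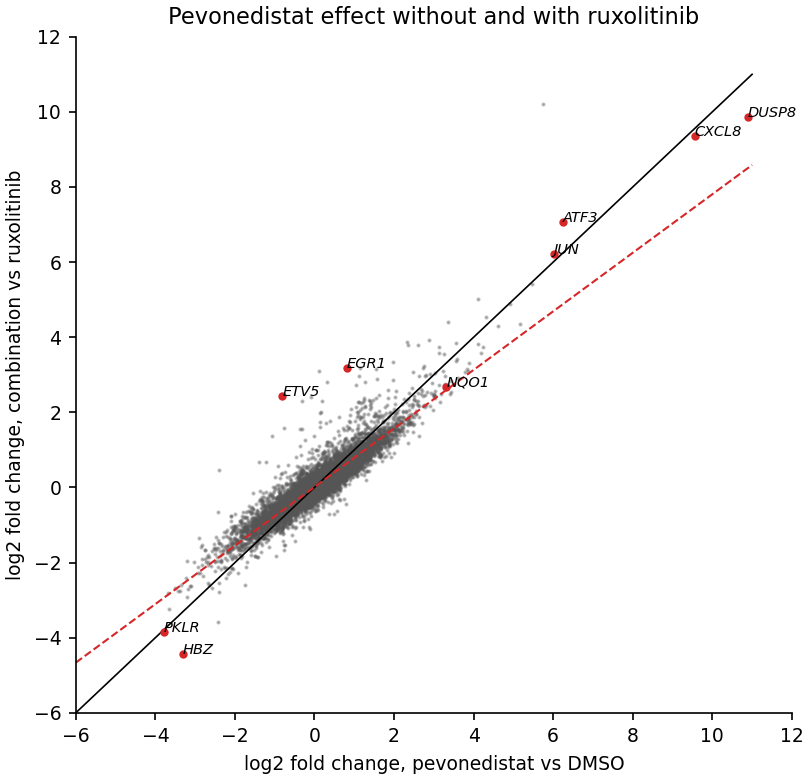
Log2 fold change of each gene with a mean of at least 5 CPM for combination against ruxolitinib (vertical) and pevonedistat against DMSO (horizontal), with a solid line of equal change and a dashed regression line of slope 0.78. Named genes are in red, and ETV5 and EGR1 lie above the line of equal change.

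The authors' deposited comparison of 14956 genes listed 2201 genes up and 2210 down for ruxolitinib, 5721 and 5737 for pevonedistat, 4925 and 4740 for the combination against DMSO, 5042 and 4892 against ruxolitinib, and 2032 and 2970 against pevonedistat. Its log2 fold changes correlated with those of edgeR across genes at r = 0.992 to 0.9994. No gene called in both had opposite signs (0 in each comparison).

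Positions of the lead genes are those of GRCh38. ETV4 (ENSG00000175832) lies on chromosome 17 from 43527844 to 43579620, ETV5 (ENSG00000244405) on chromosome 3 from 186046308 to 186110318, SOCS3 (ENSG00000184557) on chromosome 17 from 78356778 to 78360077 and PIM1 (ENSG00000137193) on chromosome 6 from 37170203 to 37175426. CXCL8 (ENSG00000169429) lies on chromosome 4 from 73740506 to 73743716, TNFAIP3 (ENSG00000118503) on chromosome 6 from 137867188 to 137883312, JUN (ENSG00000177606) on chromosome 1 from 58780788 to 58784327 and DUSP8 (ENSG00000184545) on chromosome 11 from 1554044 to 1571920. HBZ (ENSG00000130656) and HBA2 (ENSG00000188536) lie on chromosome 16, from 152687 to 154503 and from 172876 to 173710. EPAS1 (ENSG00000116016) lies on chromosome 2 from 46293667 to 46386703. Values are counts over the whole gene as the deposited table gives them.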

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

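The tests of scaling, of cytoplasmic RNA between groups for mitochondrial RNA, of counting noise and of directions by the level with ruxolitinib or DMSO, of summed histone counts and of S phase were chosen only after the result was seen, as were the gene families and the genes named here outside the fixed rule.

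The edgeR interaction test drew attention to 3135 genes whose change with pevonedistat differed with and without ruxolitinib, 14.4% of the 21776 tested. Among them were 127 of the 238 genes named in the pairwise comparisons. Most of those were named for large changes in these same libraries, so their higher share is no separate result. Differences were 3.24 for ETV5, 2.88 for SLC34A1, 2.61 for CD24, 2.51 for GP6 and 2.49 for ETV4 on the log2 scale, and -1.26 for RAB5IF, -1.18 for PRNP, -1.17 for UBXN10 and -1.16 for ADD2. Among JAK-STAT genes they were 1.19 for SOCS1, 1.17 for SOCS3, -0.35 for SOCS2, 0.30 for PIM1, 0.52 for PIM2 and 0.52 for BCL2L1. Both subunits of the NEDD8-activating enzyme had positive values, 0.41 for NAE1 and 0.34 for UBA3. The others were -0.63 for NQO1, 0.56 for HMOX1, -0.59 for CDKN1A, -0.33 for CDKN1B and 0.39 for the platelet integrin ITGA2B.

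These 13 lists, given here with camera's adjusted p at the preset correlation, differed in the same contrast. Higher were megakaryocyte genes (17 of 30 higher, 0 lower, adjusted p = 1.69e-19), mitochondrially encoded mRNAs (13 of 13 higher, adjusted p = 9.89e-17), MAPK output (7 of 24 higher, 1 lower, adjusted p = 8.13e-13), cholesterol genes (11 of 29 higher, 0 lower, adjusted p = 5.52e-06), hypoxia-inducible genes (12 of 30 higher, 2 lower, adjusted p = 2.05e-05), JAK-STAT5 output (8 of 21 higher, 3 lower, adjusted p = 0.00371), lymphocyte and stromal markers (3 of 16 higher, 0 lower, adjusted p = 0.00371) and mitosis genes (6 of 40 higher, 1 lower, adjusted p = 0.0162). Lower were erythroid genes (14 of 43 lower, 2 higher, adjusted p = 2.27e-06), ribosome biogenesis (11 of 37 lower, 1 higher, adjusted p = 3.51e-05), NRF2 targets (10 of 30 lower, 2 higher, adjusted p = 0.00089), DNA replication (8 of 48 lower, 1 higher, adjusted p = 0.003) and interferon-stimulated genes (7 of 38 lower, 2 higher, adjusted p = 0.0478). Left-out libraries ended the calls of mitosis genes (adjusted p = 0.176, 0.0892 and 0.845 without DMSO replicate 1, ruxolitinib replicate 1 and combination replicate 1), of replication genes (0.165 without combination replicate 2) and of interferon genes (0.152, 0.0727, 0.0532 and 0.0868 without DMSO replicate 2, ruxolitinib replicate 1, pevonedistat replicate 1 and combination replicate 2). The calls of NRF2 targets (0.0564), replication genes (0.121) and interferon genes (0.238) also ended at 5 CPM or more, that of mitosis genes with RLE size factors (0.0629) and that of interferon genes with the replicate block (0.0534). No call among the 13 held with an estimated correlation (lowest adjusted p = 0.102).

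Mitochondrially encoded RNA was higher with pevonedistat and highest with both drugs. A scaling factor moves all genes alike, and is argued against as the whole of the rise with pevonedistat. The median of the 13 mRNAs lay 1.16 (SD 0.39) above that of all genes. No such factor can alter that gap, so this restates the pattern and is no further support for it. Loss of cytoplasmic RNA would raise RNAs kept in the nucleus by about as much. The median of 5 such RNAs was -0.27 (SD 1.07) with pevonedistat against 1.10 for the mRNAs. MALAT1 rose (0.88) and KCNQ1OT1 fell (-2.05), so RNAs this few and this spread cannot decide for pevonedistat. In the combination over pevonedistat the median was 0.27 (SD 0.22, highest 0.65) against 0.99. In combination replicate 2 over replicate 1 it was 0.10 (SD 0.16, highest 0.38) against 0.68. These RNAs may respond to the drugs themselves, so they cannot decide for the combination over pevonedistat either. The 2 combination replicates had the same drugs. Between them loss of cytoplasmic RNA is argued against as the whole of the difference, on 5 RNAs and single libraries only. A change in mitochondrial RNA itself may remain, as a hypothesis with no direct test here.

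NF-kB target mRNAs were higher with pevonedistat. A scaling factor that moves all genes alike was argued against, since the list's median lay 1.42 (SE 0.45) above that of all genes. No such factor can alter that gap, so this restates the pattern and is no further support for it. Of 19 members with at least 5 CPM in the ruxolitinib libraries, which this comparison does not use, 18 changed. Most genes did at such levels: 8745 of 10811 changed when genes with a mean of at least 5 CPM were tested. An adjusted p under 0.05 already allows for counting noise, so the count of members is not a separate test of it. Whether members near the floor, which can hardly fall, set the balance of directions cannot be told apart. The test fixed beforehand, on 28 members with a mean of at least 5 CPM (21 rose and 5 fell), decides nothing, since the rise itself lifts that mean. Of the 19 members 13 rose and 5 fell (exact binomial p = 0.0963, two-sided, with members not independent of each other), and of 22 at that level with DMSO 14 rose and 6 fell (p = 0.115). Members on no other list had a median of 1.45 (SE 0.5, n = 34, 25 up and 5 down). The rise was thus not confined to the 5 shared members. Leaving out so few could not have brought the median to 0 once 27 of 39 rose, so this is no further support. A transcriptional response that may include NF-kB or AP-1 activity stays open as a hypothesis, and protein activity was not measured.

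Clustered histone mRNAs, which mostly lack poly(A) tails, were higher with pevonedistat: 55 of 56 rose and 0 fell, with a median of 2.53 (adjusted p = 3.9e-13, and adjusted p = 0.351 with an estimated correlation). Reads passed from some near-identical copies to others within this family would lower some as they raise others, and are argued against as the whole of it by the pattern's own values: 0 fell, and the summed level rose 5.61-fold, from 76.3 ± 4.1 to 427.8 ± 0.4 CPM. Reads shared with genes outside the family were not tested. Carry-over of RNAs without poly(A) tails cannot be told apart: 13 such RNAs had a median of 2.96 (SD 2.34), 11 rose and 2 fell, which is what the test fixed beforehand asked of that explanation. The abundant RN7SL2 (-0.28 ± 0.08) and RN7SL3 (-0.41 ± 0.14) fell, and a condition that such abundant members must also rise was added only after these values were seen; without it the test would have favoured carry-over. More cells in S phase may contribute and cannot be told apart either, since 20 of 48 replication genes rose and 18 fell (adjusted p = 0.979 with an estimated correlation).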

How the results depend on the processing

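Leaving mitochondrial genes out was chosen only after their shares were seen; the other alternatives were planned.

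Of 565 results for 241 named genes, 496 kept their direction and their side of the threshold under every alternative that covered them. The other 69 differed under at least 1, and 1 changed direction. That was BCL2L1 in the combination against ruxolitinib, 0.16 here and -0.017 with total-count scaling, whose own shift of all genes is larger than the value. Not covered were genes under 5 CPM in the fit above that level, the interaction with only the groups compared, and mitochondrial genes where left out. With libraries left out, 4392 of 4520 named-gene values stayed as they were, 118 lost the threshold and 10 gained it. Under the other alternatives 5497 of 5568 stayed, 42 lost the threshold and 28 gained it.

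Counts of changed genes ran, over the libraries left out, from 1573 (without DMSO replicate 1) to 3854 (without combination replicate 1) for ruxolitinib against DMSO, with 1763 and 1590 without ruxolitinib replicates 1 and 2, and from 1889 (without ruxolitinib replicate 2) to 3685 for the interaction, with 2080 without DMSO replicate 1. They ran from 11095 to 13131 for pevonedistat, 9498 to 10798 for the combination against DMSO, 9316 to 10881 against ruxolitinib and 3761 to 5542 against pevonedistat. A group left with a single library is assumed to vary like the others, and fewer libraries lower the power. Under the other alternatives they ran from 2595 to 4273, 8745 to 12974, 8148 to 11177, 8201 to 11051 and 4777 to 5815 for the pairwise comparisons in the order above, ruxolitinib first, and from 2682 to 3622 for the interaction. Fitting only the groups compared could not be done for the interaction, which uses all 4.

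Libraries with the same replicate number showed no strong shared effect: the replicate differences of different groups correlated at -0.137 to 0.064. This cannot show whether they were prepared together. With the number as a replicate block, counts were 2616 for ruxolitinib, 12344 for pevonedistat, 10633, 10625 and 5059 for the combination against DMSO, ruxolitinib and pevonedistat, 2753 for the interaction, and 75 list calls.

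Of 120 list tests 76 were called, 3 with an estimated correlation, 77 with RLE size factors, 64 at 5 CPM or more, and 71 to 80 with a library left out. The sign of the median, mean and test differed for 1, 5, 4, 1, 3 and 2 lists in the 6 contrasts, 0 of them called, and fry called 8, 15, 15, 16, 12 and 4 lists. Mitosis genes in the combination against pevonedistat had an adjusted p of 0.785 upward, and without combination replicate 1 were called lower (0.0275) and without combination replicate 2 higher (0.0295), over a range of 0.0275 to 0.908 with libraries left out; the cause was not tested.

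The correlation of pevonedistat effects with and without ruxolitinib was 0.762, 0.656 to 0.738 with a library left out, 0.925 at 5 CPM or more and 0.867 over genes called for pevonedistat alone. That of ruxolitinib effects was 0.128, 0.09 to 0.14, 0.353 and 0.397. Genes under 5 CPM are where depth limits the calls: 10811 of the 21776 tested reach that level.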

Other observations

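The gene families, individual RNAs and tests in this part were chosen only after their values were seen.

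Beyond the lists, host genes of small nucleolar RNAs rose with pevonedistat, 16 of 25 up and 6 down with a median log2 fold change of 1.04, including GAS5 (2.39 ± 0.07), whose spliced transcript is a target of nonsense-mediated decay; SNHG1 was at 2.37 ± 0.06 with both drugs against DMSO. Camera's adjusted p was 6e-15 with pevonedistat and 0.0625 with an estimated correlation; for the combination the call held with an estimated correlation against DMSO (adjusted p = 0.0359) and against ruxolitinib (adjusted p = 0.0451). Proteasome subunits rose with pevonedistat in 29 of 46 cases and fell in 4 (adjusted p = 0.00974, and adjusted p = 0.61 with an estimated correlation), and were lower with the combination than with pevonedistat in 28 and higher in 2 (adjusted p = 5.76e-12, and adjusted p = 0.316 with an estimated correlation). Tubulin genes fell with pevonedistat in 15 of 24 cases and rose in 4 (adjusted p = 1.69e-05, and adjusted p = 0.122 with an estimated correlation). Zinc-finger genes of the ZNF family had 270 of 489 up and 79 down (adjusted p = 2.26e-06, and adjusted p = 0.122 with an estimated correlation).

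Metallothioneins, which bind zinc and copper, were lower with both drugs than with DMSO in 5 of 5 genes, with a median of -2.04 (adjusted p = 0.000817, and adjusted p = 0.176 with an estimated correlation). MT2A, the most abundant of them at a mean of 38.3 CPM, fell by 0.78 on the log2 scale with ruxolitinib, by 0.92 with pevonedistat and by 1.87 with both. The others had means of only 0.39 (MT1G) to 1.70 CPM (MT1X), near the floor. The family's median is the value of MT1X (-2.04 ± 0.26) and so rests on few counts. Among histone genes outside the clusters H3-3B (1.05 ± 0.06) rose with pevonedistat while H3-3A (-0.66 ± 0.07) and MACROH2A1 (-0.80 ± 0.06) fell. The mitochondrial ribosomal RNA MT-RNR1 was higher with ruxolitinib (1.74 ± 0.16), and MT-RNR2 was at 0.29 ± 0.11 (adjusted p = 0.0935). The small nuclear RNAs RNU1-2 (3.79 ± 0.68) and RNU5E-1 (3.47 ± 0.51) rose with pevonedistat from under 1 CPM.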
